A study of Homo sapiens with 8 samples.

How the data were processed

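RNA from 2 established human colorectal cancer cell lines, LoVo and GP5d, was measured on gene expression arrays. LoVo is a colon adenocarcinoma line derived from a metastasis. Per the labels' protocols, cells were cultured in a serum-containing medium, total RNA was column-purified, and biotin-labelled cRNA was made for Affymetrix arrays. The labels name 4 biological replicates of each line, so 8 arrays in all, and do not say whether replicates of the 2 lines shared a culture day, a labelling round or a scan. The array type and the scan dates are not given in the sources used here.

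The authors deposited 1 table of log2 values with 19002 rows and 8 columns, 1 column per array, and all 8 were used. The scale was settled from the values. They ran from 0.472 to 14.7, which a 16-bit scanner can give only if the base of the logarithm is 2. Every row name is an Ensembl human gene ID followed by "_at", so probes had been grouped by gene before summarisation. The version of that grouping is not given in the sources used here. RMA and GCRMA are both named, per the submitters' processing notes, without a role. Both correct the background, normalize arrays together and summarise probes, and which of them made the table stayed unknown. The quantiles of the 8 columns lay close together, with column medians between 3.05 and 3.11, so the values were taken to come from 1 common normalization and were compared without further scaling. Genes were not centred. No detection calls or control probe sets were used here.

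The deposited table does not pair the IDs with gene names. The reference gene table at hand listed 59792 genes, 0 of them with an Ensembl ID, and so 0 of the 19002 row IDs could be matched to a symbol or a chromosome. Names were not filled in from memory. As a result, the 30 gene lists, the list of single genes and the comparison of chromosomes that had been fixed before the data were examined were not run. At most 2 IDs per direction are printed. They were taken in order from the rule fixed beforehand: the largest absolute log2 differences among called genes whose 4 values of one line do not overlap the 4 of the other, and whose mean in the higher line is above the 60th percentile of all gene means, a log2 value of 4.16. That rule leaves out XIST and genes of chromosome Y, and this exception could not be looked up for the IDs.

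The lines were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, line as the only factor, all 8 arrays, 6 residual degrees of freedom) on the log2 values as deposited, and p-values were adjusted by the Benjamini-Hochberg method over all 19002 genes. A gene was called where its adjusted p was under 0.05 and its absolute log2 difference was at least 1, a 2-fold difference. With 1 row per gene, no rule for choosing between probe sets was needed. Differences are LoVo minus GP5d. Data were also simulated with the pooled within-line spread of these arrays, with 200 of the 19002 genes changed. Of 50 genes changed by each size, 0 were called at a log2 change of 0.5 and 48 at 1.5. At changes of 2 and 3, 50 and 49 were called. There were 0 false calls. The result at 0.5 largely follows from the minimum difference, and no size close to 1 was simulated. The noise was normal and independent, with the same spread in both lines, so the run does not measure false calls in the real data.

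The values form a tall peak at the low end of the scale. After the distribution had been seen, its upper end was set at the mode (1.87) plus 3 times the SD of the values below the mode (0.311), which gave 2.81 on the log2 scale. Values at or below it, 46.1% of all values, are called the low peak. Such values have no reliable order, and background correction and probe affinity decide much of them. For a gene in the low peak on all 4 arrays of a line, a fold is therefore also given as a lower bound, with each of those values raised to 2.81. Probes that hybridise to related genes were not separated out here, so genes with near-identical copies are uncertain. Arrays give no read depth, and the number of arrays limits the precision: the median standard error of a log2 difference was 0.109.

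Alternatives fixed before the data were examined were 3 further between-array normalizations, a filter on dim genes, a floor on low values, a trended and robust variance prior, array weights, the replicate number as a block, each array left out in turn, other minimum differences and limma's treat test. Alternative ends of the low peak were added after seeing the data. Of the 28 pairs of arrays, 5 held exactly the same value at 1 gene and the others at none. Plots were drawn with matplotlib 3.10.9.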

Results

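LoVo and GP5d are lines of human colorectal cancer cells that were grown in culture, and the transcriptome of each was profiled on 4 arrays. The comparison asked which genes the 2 lines express at different levels. Each array gave a log2 value for 19002 genes, each identified by an Ensembl gene ID. The IDs could not be paired with gene names here, so genes are described by their level and number, and a few by ID. Arrays of the same line resembled each other more than arrays of different lines. Pearson correlations across genes lay between 0.9973 and 0.9984 among the GP5d arrays, between 0.989 and 0.9965 among the LoVo arrays and between 0.9467 and 0.9525 across lines. Genes are not independent replicates, so these values describe the arrays only.

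The replicates of LoVo were less alike than those of GP5d, and 1 array accounted for most of this. LoVo replicate 3 correlated with the other LoVo arrays at 0.989 to 0.9909, whereas the other 3 LoVo arrays correlated with each other at 0.9956 to 0.9965. Among the 10361 genes whose mean lay above the low peak, the median SD between replicates was 0.193 in LoVo and 0.104 in GP5d (n = 4 each). Without LoVo replicate 3 the LoVo value was 0.132 (n = 3). For comparison, sets of 3 GP5d arrays gave 0.095 to 0.101.

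The lines shared most of the genes found above the low peak. Of the 19002 genes, 8980 (47.3%) lay above the low peak on all 8 arrays and 7307 (38.5%) lay within it on all 8. A further 299 genes were above the peak on the 4 LoVo arrays and within it on the 4 GP5d arrays, and 366 showed the opposite. The remaining 2050 genes were not on 1 side of the limit in all arrays of each line. Per array, 10232 ± 149 genes (SD, n = 4) were above the low peak in LoVo and 10250 ± 20.2 (SD, n = 4) in GP5d, a difference that did not pass an exact two-sided permutation test over 70 assignments (p = 0.943). LoVo replicate 3 alone had 10456 genes above the limit. Without it the LoVo value was 10157 ± 7.51 (SD, n = 3), with an exact permutation p = 0.0286, the smallest that 35 assignments can give, but that array stood apart partly in this same measure. With all 8 arrays the direction also depended on the scaling and on the limit, as LoVo minus GP5d was 49.75 with a common median and 141.2 with a limit of 2 SDs above the mode, and so no difference between the lines was established.

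**Figure D1:**
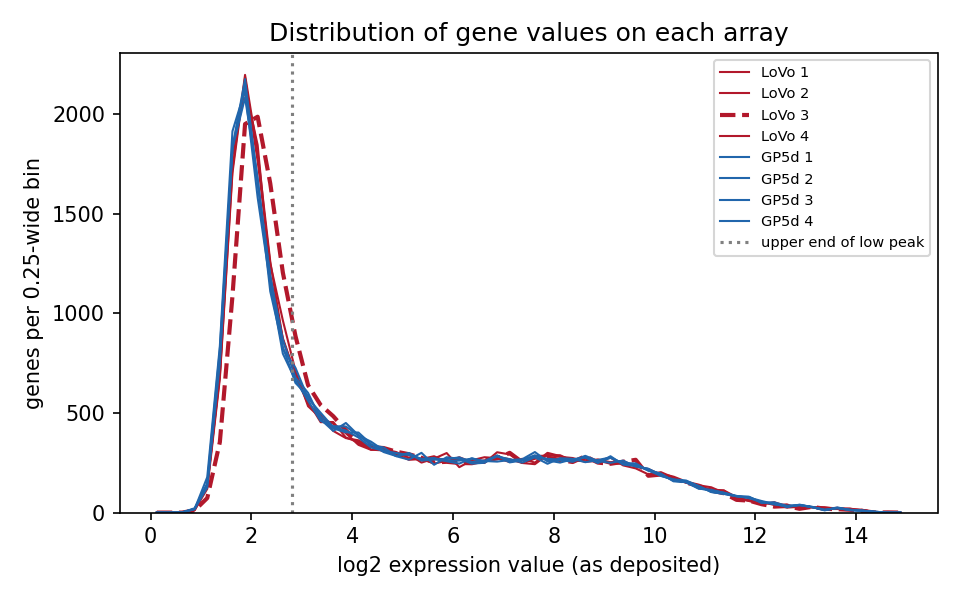
Number of genes per 0.25-wide bin (vertical axis) against the log2 value as deposited (horizontal axis), 1 line per array, red for LoVo and blue for GP5d; the dotted line marks the upper end of the low peak at 2.81. The dashed curve of LoVo replicate 3 lies to the right of the other 7 in the low peak, with a 25th percentile of 2.15 against 1.96 to 2.01 on the others.

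The 2 lines were called different, with an estimated difference of 2-fold or more, at 2530 genes, 13.3% of those tested. Of these, 1162 were higher in LoVo and 1368 (54.1%) were higher in GP5d (limma, adjusted p under 0.05). The adjusted p tests a difference from 0, not a difference above 2-fold. Limma's treat, which tests against the 2-fold limit, called 1250 genes at the same adjusted p, 581 higher in LoVo and 669 higher in GP5d. At 2513 of the 2530 called genes (99.3%) the 4 values of one line did not overlap the 4 of the other. Among all tested genes this held for 44.1%, and chance alone would give 2.86%. The call used the same arrays and favours genes without overlap, so the 99.3% is no separate support for it. Without LoVo replicate 3, the array that stood apart, 2561 genes were called, 1215 higher in LoVo and 1346 higher in GP5d, and 2381 of them were among the 2530. On the adjusted p alone, with no minimum difference, 8230 genes (43.3%) passed, 4076 of them higher in LoVo and 4154 higher in GP5d. Most of these differences were therefore smaller than 2-fold (5700 genes), and only 1 gene with a 2-fold difference missed the adjusted p.

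Most called genes differed in level between lines that both had them above the low peak. Of the 8980 genes above the peak on all 8 arrays, 1765 (19.7%) were called, 838 higher in LoVo and 927 higher in GP5d. The median absolute difference of all called genes was 1.50 on the log2 scale. Calls were most frequent at intermediate mean levels. Of the 2525 genes with a mean log2 value between 4 and 6 over all 8 arrays, 29.9% were called. The share was 12.3% of the 1197 genes above 10 and 1.79% of the 8641 genes with a mean in the low peak. This grouping builds in part of the pattern. A gene high in one line and low in the other has an intermediate mean. A mean in the low peak leaves little room for a 2-fold difference.

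Large differences were found in both directions. They were counted with every value in the low peak raised to its upper end, so that each is a lower bound. On that scale 639 called genes differed by at least 4-fold, 312 higher in LoVo and 327 higher in GP5d, and 160 by at least 16-fold, 87 and 73. At least a 64-fold difference was found for 26 genes higher in LoVo and 17 higher in GP5d. On the values as deposited these counts were 348 and 373, 94 and 87, and 33 and 27. Of the 2530 called genes, 2295 still differed by at least 2-fold on the bounded scale. Neither these bounded counts nor the bounded folds of single genes were repeated with another limit. A clear split, with all 4 arrays of one line in the low peak and all 4 of the other above 4.16, was seen for 185 of the called genes. Of these, 86 were high in LoVo and 99 were high in GP5d. The counts were 95 and 116 without LoVo replicate 3. They depended on the end chosen for the low peak, with 47 and 57 for a limit of 2 SDs above the mode and 114 and 142 for 4 SDs.

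**Figure D2:**
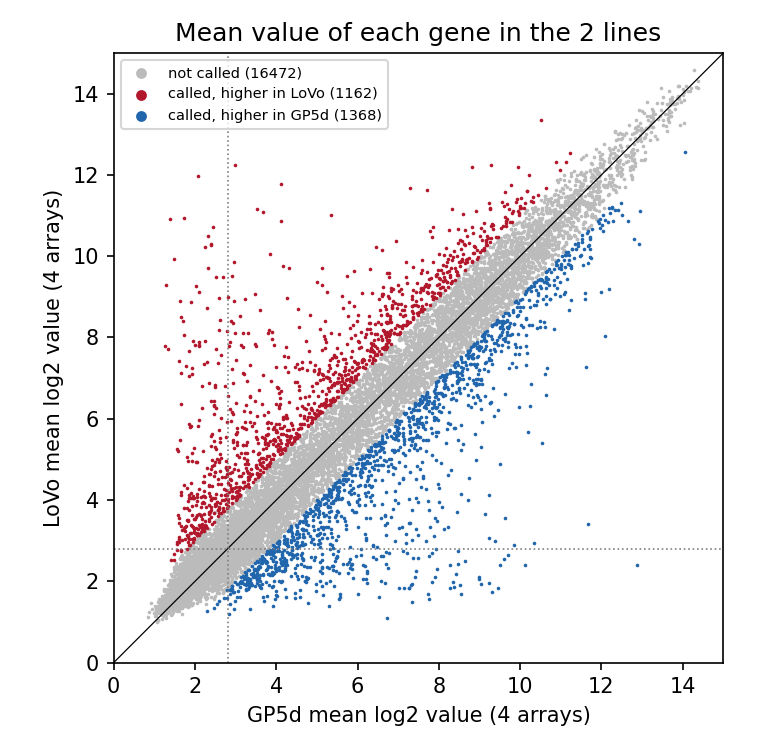
Mean log2 value of each gene in LoVo (vertical axis) against GP5d (horizontal axis), each over 4 arrays; red points are the 1162 genes called higher in LoVo, blue points the 1368 called higher in GP5d, grey points the rest, and dotted lines mark the upper end of the low peak. Called genes lie on both sides of the diagonal, and those in the low peak in one line form the vertical and horizontal bands at the left and bottom.

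The largest difference of any gene on the deposited scale was at ENSG00000148346_at, which was among the higher values of the array in GP5d, at 12.88 ± 0.248 (SD, n = 4), and in the low peak in LoVo, at 2.40 ± 0.163 (SD, n = 4). Its log2 difference was -10.48 (SE 0.133, limma adjusted p = 1.56e-11), and GP5d was at least 1076-fold higher when the LoVo values were set to the end of the low peak. The next gene higher in GP5d was ENSG00000176046_at, with 11.68 ± 0.184 in GP5d and 3.40 ± 0.504 in LoVo (SD, n = 4 each) and a log2 difference of -8.28 (SE 0.220, limma adjusted p = 1.86e-09), 311-fold on the deposited scale. In the other direction, ENSG00000133710_at was at 11.98 ± 0.259 in LoVo and 2.06 ± 0.274 in GP5d (SD, n = 4 each). Its log2 difference was 9.92 (SE 0.162, limma adjusted p = 7.06e-11), and LoVo was at least 578-fold higher. ENSG00000107984_at was at 10.91 ± 0.189 in LoVo and 1.39 ± 0.110 in GP5d (SD, n = 4 each), a log2 difference of 9.53 (SE 0.108, limma adjusted p = 1.16e-11), with LoVo at least 276-fold higher. By the bounded difference the GP5d-high genes kept the ranks 1 and 2 among the genes the rule admits, while ENSG00000133710_at ranked 2 and ENSG00000107984_at ranked 4 among the LoVo-high genes. The rule that chose these genes required that the lines do not overlap.

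**Figure D3:**
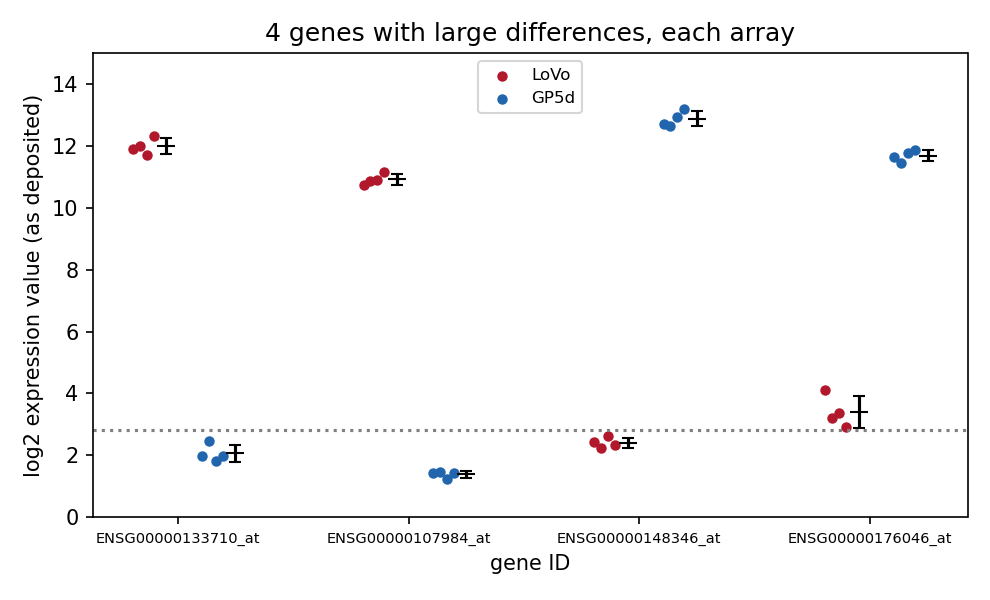
Log2 value as deposited (vertical axis) of 4 genes (horizontal axis), the 2 in each direction with the largest differences on the deposited scale, on every array, red for LoVo and blue for GP5d, with the mean and SD of the 4 arrays in black; the dotted line marks the upper end of the low peak. The lines do not overlap at the 4 genes, as the rule that chose them required, and the LoVo values of ENSG00000176046_at lie just above the low peak, from 2.92 to 4.10.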

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

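The tests of LoVo replicate 3 and of the low peak were chosen after these patterns had been seen, and before their own outcomes were seen. In 30 comparisons of the 4 arrays of a line, each asking whether 1 array lay far from the other 3 (Dixon's test), 7 pointed to an array, where chance would give about 1 in 20, and each of the 7 pointed to LoVo replicate 3. Its 10th percentile was 1.81, its 25th percentile 2.15, its median 3.11 and its 75th percentile 6.57. It had 10456 genes above the low peak, a mean correlation of 0.990 with the other LoVo arrays and an SD of 0.406 for its deviations from their mean. These measures come from the same array and are not independent of each other.

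LoVo replicate 3 thus had higher low values and a lower upper quartile than the other LoVo arrays, and its genes scattered more. A shift that depends only on level may explain the first part but not the scatter: after a smooth curve of deviation on level was removed, the SD of its deviations was still 0.385, against 0.232 to 0.260 on the other 3 LoVo arrays. Admixture of GP5d RNA was argued against as the whole cause, because the SD was 0.392 among 2036 genes that the other LoVo arrays and GP5d had at like levels, against 0.200 to 0.240 on the other arrays. A small admixture was not excluded: 116 genes low in the other LoVo arrays and high in GP5d were higher in replicate 3 by a median of 0.199, against 0.146 for 7630 genes low in both lines. RNA quality, labelling, hybridisation and a different state of the culture stay open and untested, and the labels name no biological difference between replicates.

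The low peak held a weak lean towards LoVo. Of the 8641 genes with a mean in it, 64.8% had a higher mean in LoVo, with a median log2 difference of 0.0685. Raised low values of LoVo replicate 3 may account for part of the lean but not for all of it, since the share was 56.4% without that array. An offset between arrays left by the normalization cannot be told apart from a difference between lines, since quantile normalization brought the share to 53.1%, between the bounds of 52% and 55% set beforehand, and cyclic loess brought it to 50.6%. Of these genes, 1.79% were called. Among the 7307 genes within the low peak on all 8 arrays, only 3 were called.

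Of the 35 splits of the 8 arrays into 4 and 4, the real one alone gave as many as its 2530 called genes (1 of 35), and the highest of the other splits gave 0 by limma. Every other split mixes the lines, so the difference between them adds to the spread within groups and holds their count down. The rank of the real split, 1 of 35, excludes a chance division of these arrays at the 0.05 level, but the 0 of the other splits is no estimate of false calls. A processing difference that coincided with the line would give the same rank. The labels do not say whether the lines shared a culture day, a labelling round or a scan. At an unadjusted p under 0.05 the other splits gave up to 1544 genes, and the real split 9427.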

How the results depend on the processing

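The count of 2530 called genes stayed between 2258 (dim genes left out) and 2580 under the alternatives that kept the call's threshold and tested a difference from 0. No called gene changed sign. With 1 array left out it was 2499 to 2580, with 1155 to 1215 genes higher in LoVo and 1339 to 1401 higher in GP5d. The genes themselves changed more: each omission lost 57 to 149 of the 2530 and gained 63 to 180. Of the 2530 genes, 2157 were called in all 8 of these fits. By construction, the minimum difference decided the count: 8230 with none (4076 higher in LoVo, 4154 in GP5d) and 721 with a log2 difference of 2 (348 and 373). The kind of test mattered too. Limma's treat kept the minimum log2 difference of 1 but tested against it, and called 1250 genes (581 and 669). The share of called genes higher in GP5d, 54.1%, moved to 51.3% with a common median, 50.5% with no minimum and 51.7% with a log2 difference of 2. The 4 named IDs kept their direction and call in all 64 alternative values. Deviations from line means did not pair by replicate number (correlations -0.0341 to 0.0488). With it as a block, 2530 genes were called, 2529 shared.

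Results on the low peak moved more. The share of its genes higher in LoVo, 64.8%, became 70.8% with a common median, 53.1% after quantile normalization and 50.6% after cyclic loess, and 56.4% (without LoVo replicate 3) to 67.0% with 1 array left out. The difference in genes above the peak, -17.75, turned to 49.75 with a common median and 141.2 with a limit of 2 SDs (exact permutation p = 0.0857 and 0.8), was 0 by construction after quantile normalization, -37.25 after cyclic loess and -69.25 with a limit of 4 SDs (p = 0.143 and 0.114 for the last 2), and was -92.42 (without LoVo replicate 3) to 9.583 with 1 array left out; the cause was not tested. The genes low in one line and high in the other, 86 and 99, were 47 and 57 with a limit of 2 SDs and 114 and 142 with 4 SDs. Probe set choices could not be varied with 1 row per gene, no pseudocount applied, and the alternatives for lists and chromosomes were not run for want of gene names. The 99th percentile lay 10.25 to 10.49 above the mode of the low peak.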

Other observations

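The 4 GP5d arrays were closer in pairs. Replicates 1 and 2 correlated at 0.9984 and replicates 3 and 4 at 0.9983, while the correlations between these pairs were 0.9973 to 0.9976. No label gives a batch for these arrays, and no explanation was tested. The GP5d SDs, their comparison with LoVo and the limma tests treated the 4 arrays as independent replicates, and this was not checked.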
